A study of Mus musculus with 12 samples.

How the data were processed

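RNA of a mouse embryonic stem cell line was measured on 12 two-colour Agilent arrays, 1 array per sample. Per the labels, on each of the 12 arrays the sample RNA carried Cy3 and a mouse reference RNA pooled from cell lines carried Cy5. There was no dye swap. A dye bias specific to a probe drops out of differences between times only where it is equal on all arrays, which was not tested. The scanner files hold intensity values per spot, made with Agilent Feature Extraction 7.5.1 per the file headers. The deposited mean and background signals are plain intensity values, and the processed signals are intensity values that the program subtracted for background and normalized between dyes with signal-dependent factors, per the file headers. The deposited series table holds log10 values. Set against the scanner files, its direction was sample over reference: each value equalled the log10 ratio of the processed signals plus the probe's mean log10 reference signal, within a tolerance of 0.001, for 88.8% to 90.1% of probes per array. The rule behind the other values is not given in the sources used here. The medians of its columns were 2.98 in each of the 12 arrays after rounding.

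Each array holds 42034 probe spots with 42006 distinct probe names and 2256 control spots. The probes are 60 bases long. The files repeat the probe name in the columns for gene and systematic name and do not pair the probes with genes, so no probe was given a gene name here. The planned readout of Sox2 and Pou5f1 in each array, which would have checked the labels, the gene lists with their set tests, the cell type markers and the choice of 1 probe per gene were therefore not run, and counts below are counts of probes, not genes. Several probes can read 1 gene, and 40 sequences were shared by more than 1 probe name. The rule for named genes was kept without its condition on gene symbols and limited to 2 probes that rose and 2 that fell: the largest changes late against 0 h among called probes whose 4 late arrays all lay on one side of both 0 h arrays.

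Mean signals were corrected for background with normexp and an offset of 50, and log2 ratios of sample over reference were normalized by loess within each array with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots with outlier flags were left out and spots of 1 probe were averaged. A probe was kept when its Cy3 signal was well above background on at least 2 arrays, which kept 41754 probes and removed 252. The offset shrinks the fold changes of dim probes. Where Cy3 or Cy5 alone is given, the channel had the same background correction and was normalized by quantiles between arrays in place of loess. Tests were made with lmFit and eBayes of limma and Benjamini-Hochberg adjustment, and a probe was called at an adjusted p under 0.05. Single times, the early mean (3, 6 and 12 h) and the late mean (48, 72 and 96 h) were compared with 0 h in 1 fit of the 8 time groups, which left 4 residual degrees of freedom. Late against early was a fit of 2 groups of 4 arrays, and the linear trend used all 12 arrays, per 24 h. These comparisons, the alternatives to them and the grouping were fixed before the data were examined. The steps between neighbouring times, the comparison of 48 to 96 h with 24 h, the transient probes and the shares of change reached were added after seeing the data. A transient probe differed at 24 h in one direction from both 0 h and the mean of 72 and 96 h, tested on the larger of both p-values.

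Times with 1 array (3, 12, 48 and 96 h) have no spread of their own and were assumed to vary like the replicated times. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Per the file headers the image analysis was run on 2 days: all 6 arrays of 0 to 12 h on the first and all 6 arrays of 24 to 96 h on the second. Comparisons within 0 to 12 h and within 24 to 96 h lie inside a day. Between them, day and time cannot be told apart in the group comparisons, while the linear trend could take day as a block.

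The fits were tested on simulated data of 41246 probes, of which 200 were changed. Independent normal noise was drawn from each probe's spread in the group fit, equal at all times and with no day effect. Far more probes were called in the real late arrays, which alters the adjustment, so the recovered shares hold for the simulated setting only. At a log2 change of 0.5, 99.0% of changed probes were recovered for 3 h against 0 h and 99.0% for late against 0 h. At a log2 change of 0.25, 0 of the 200 were recovered for 3 h against 0 h, 48.5% for 24 h, 76.5% for early, 73.0% for late, 95.0% for late against early and 81.5% for a trend reaching that size at 96 h. Figures were drawn with matplotlib 3.10.9.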

Results

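Expression was followed in 2TS22C, a mouse embryonic stem cell line in which tetracycline (Tc) switches off the remaining supply of the transcription factor Sox2, grown with the cytokine LIF. Cells were harvested untreated (0 h) or 3, 6, 12, 24, 48, 72 and 96 h after Tc was added, with 2 arrays at 0, 6, 24 and 72 h and 1 array at 3, 12, 48 and 96 h. The titles and the series design give Tc to all samples after 0 h, whereas the description field writes the untreated form for every sample; the titles were followed. Which probe reads Sox2 is not given in the sources used here, so the switch itself was not checked. The median Cy3 signal over background ranged from 97.0 to 221 units and 93.4% to 99.8% of probes were well above background in Cy3. Both dyes split by image analysis day without overlap. The Cy3 median was 97.0 to 120 units on the arrays of 0 to 12 h and 122 to 221 on those of 24 to 96 h. For Cy5, with the same reference RNA on every array, it was 229 to 283 and 335 to 429 units. The SD between replicate arrays was 0.06 log2 units at 0, 6 and 24 h and 0.08 at 72 h.

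Arrays departed from the untreated state steadily with time. Across probes, which are not independent replicates, the correlation of log2 ratios with the 0 h mean was 0.994 at 3 h, 0.983 at 12 h, 0.965 and 0.966 at 24 h, 0.923 at 48 h, 0.886 and 0.895 at 72 h and 0.840 at 96 h. Each array of a replicated time correlated best with its own replicate.

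**Figure D1:**
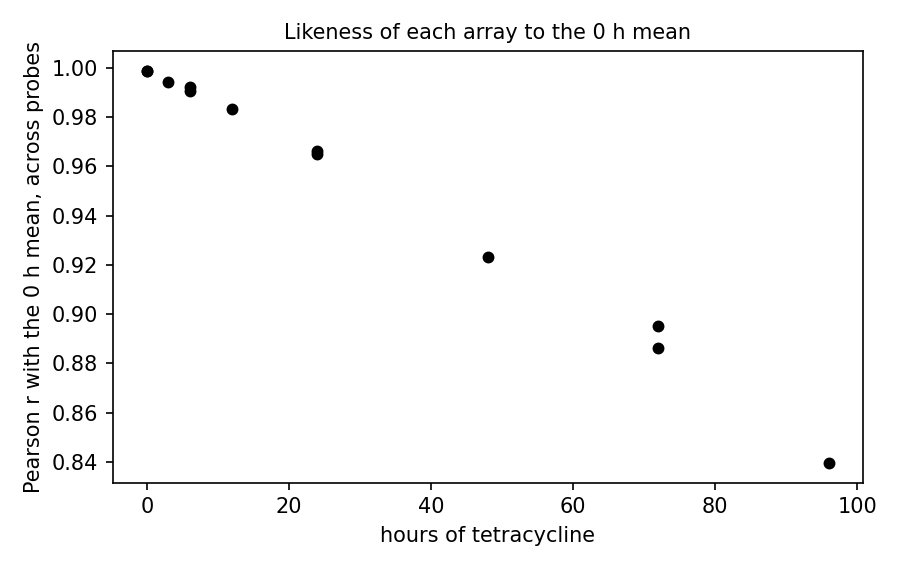
Pearson correlation across probes of each array's log2 ratios with the mean of both 0 h arrays (vertical axis) by hours of Tc (horizontal axis), 1 point per array. The values fall from 0.994 at 3 h to 0.840 at 96 h; both 0 h arrays are part of the mean they are compared with.

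The first question was how soon expression moved after Tc. At 3 h 10 probes were called, 7 higher and 3 lower than at 0 h, with limma at an adjusted p under 0.05. Of these, 4 rose at least 2-fold, and all 4 fell at least 2-fold again from 3 h to 6 h; 1 of these 4, and 4 of the 10, were also called at 6 h against 0 h. Without the first 0 h array 4 probes were called at 3 h. At 6 h 656 probes were called (359 rose, 297 fell), none by 2-fold, and at 12 h 2207 (1160 rose, 1047 fell), of which 9 rose and 36 fell at least 2-fold. The mean of 3, 6 and 12 h differed from 0 h for 1093 probes, 563 higher and 530 lower, with median changes of 0.26 and -0.24 log2 units. These arrays share 1 image analysis day. For the 4 probes that rose and fell again, both comparisons use the single 3 h array, so the fall is no independent check. At 12 h falls outnumbered rises with an offset of 0, the processed signals and the deposited table, but not with Cy3 alone or median centring. The early calls depended on single arrays and on the signal used: without the 12 h array 38 probes were called early, without the 3 h array 2354, without either 0 h array 151 or 209, without the second 6 h array 689, and with Agilent's processed signals 110. The 6 h count fell to 1 with the processed signals, to 0 with Cy3 alone, to 41 or 54 without either 0 h array and to 111 or 51 without either 6 h array.

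From 24 h on the changes were broad. At 24 h 7507 probes were called, 4381 higher and 3126 lower, at 48 h 10496 (6156 and 4340), at 72 h 14085 (7791 and 6294) and at 96 h 15579 (8785 and 6794). Among changes of at least 2-fold, falls outnumbered rises at 24 h (141 against 66), whereas rises outnumbered falls at 96 h (1295 against 680). The 24 h count was 4873 or 4817 without either 0 h array and 2747 with Cy3 alone, where 47.8% of the calls were rises in place of 58.4%. Cy3 alone called 5280 at 48 h, 8970 at 72 h (4436 rises and 4534 falls) and 10748 at 96 h (4993 rises and 5755 falls), so the majority of rises at 72 and 96 h was lost in that channel; the 12 h count was 1146 or 1145 without either 0 h array. Cy3 alone was also normalized by quantiles between arrays, unlike the ratios, so for this loss the channel and the normalization cannot be told apart. The times from 24 h on were read on another image analysis day than 0 h, so that for single times day and time cannot be told apart.

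**Figure D2:**
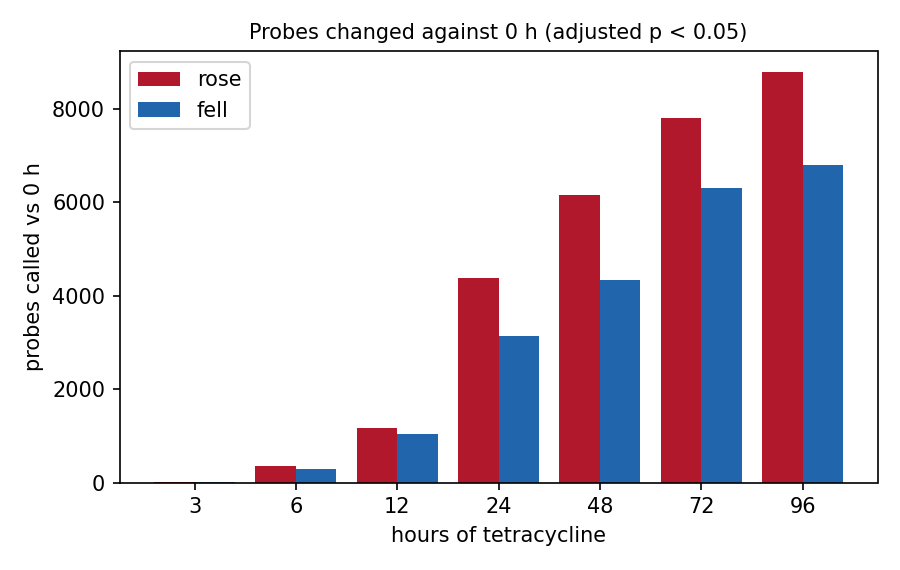
Number of probes called against 0 h (vertical axis) at each time of Tc (horizontal axis, hours), with rises and falls as separate bars. The rises grow from 7 at 3 h to 8785 at 96 h and the falls from 3 to 6794.

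Late samples (48, 72 and 96 h) differed from 0 h for 16136 of 41607 probes, of which 8911 rose and 7225 fell, with median changes of 0.34 and -0.27 log2 units. At least 2-fold, 675 rose and 454 fell. For 7974 of the risers and 6566 of the fallers the 4 late arrays lay without overlap on one side of both 0 h arrays. Over all tested probes, 23.4% lay above and 23.4% below without overlap, where chance gives 6.67% per direction. With Cy3 alone 10747 probes were called, 48.4% of them rises against 55.2% with ratios.

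The largest rise was that of probe Z00015331-1 (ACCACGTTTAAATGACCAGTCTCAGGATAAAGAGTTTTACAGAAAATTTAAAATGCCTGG), whose log2 ratio of sample over reference went from -2.12 ± 0.05 (SD, n = 2) at 0 h to 1.05 ± 0.71 (SD, n = 4) over the late arrays. Its fitted change was 3.13 (SE 0.05, limma adjusted p = 2.51e-10), with 0.67 at 24 h, 2.21 at 48 h and 3.93 at 96 h. Probe Z00000270-1 (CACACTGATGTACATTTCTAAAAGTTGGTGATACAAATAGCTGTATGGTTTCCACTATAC) rose from 1.04 ± 0.06 (SD, n = 2) to 3.83 ± 0.54 (SD, n = 4), a fitted change of 2.69 (SE 0.10, limma adjusted p = 1.01e-08). The largest fall was that of Z00026066-1 (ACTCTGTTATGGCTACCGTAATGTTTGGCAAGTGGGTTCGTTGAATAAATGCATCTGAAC), from 4.65 ± 0.17 (SD, n = 2) to 0.79 ± 0.11 (SD, n = 4), a fitted change of -3.87 (SE 0.11, limma adjusted p = 2.29e-09), whereas Cy3 alone gave -5.53; its net Cy5 signal was also lower on the 4 late arrays than on both 0 h arrays. Probe Z00036522-1 (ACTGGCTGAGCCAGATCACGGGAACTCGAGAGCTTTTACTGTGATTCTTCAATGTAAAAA) changed by -3.34 (SE 0.04, limma adjusted p = 1.18e-10); its log2 ratio was -0.10 at 12 h, -2.54 ± 0.09 (SD, n = 2) at 24 h and -3.62 at 48 h. None of these 4 probes was called at 3, 6 or 12 h, and each was well above background in Cy3 on all 12 arrays. Except for Z00026066-1, their net Cy5 signals were higher on the 4 late arrays than on both 0 h arrays. For Z00000270-1 it went from 187 and 172 units at 0 h to 554 at 96 h, and Cy3 alone gave a change of 3.15. Over all probes the median net Cy5 signal was 283 and 271 units at 0 h and 429 at 96 h.

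**Figure D3:**
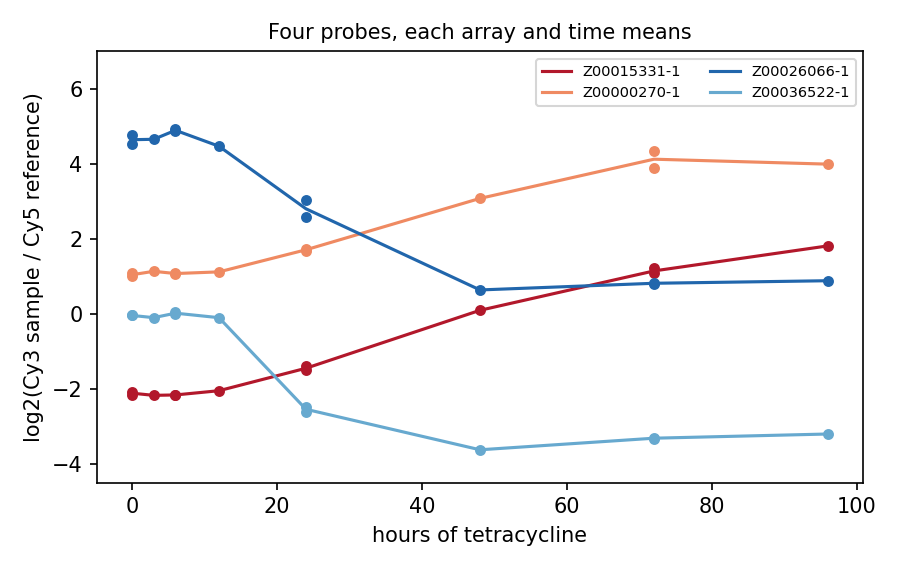
Log2 ratio of Cy3 sample over Cy5 reference (vertical axis) by hours of Tc (horizontal axis) for 2 probes that rose and 2 that fell; points are arrays and lines join the time means. Z00036522-1 stands at -0.10 at 12 h and -2.54 at 24 h, whereas Z00015331-1 goes on rising to 1.81 at 96 h.

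Late arrays differed from the early treated arrays, 4 against 4, for 14415 of 41752 probes, 8083 higher and 6332 lower late, and 602 and 461 of them at least 2-fold. With Cy3 alone 7580 were higher and 7556 lower late. All early arrays were read on the first day and all late arrays on the second. A linear trend over time was called for 16351 probes (8990 rising, 7361 falling), with median slopes of 0.11 and -0.09 log2 units per 24 h. The Cy5 channel alone, although it held the same reference RNA on every array, had a trend for 10564 probes (4881 rising, 5683 falling). With the day as a block 11130 probes had a trend, within the first day 2140 and within the second 10154.

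Each step between neighbouring times set 1 array against 2, so their precision was alike (median SE 0.06 log2 units). From 0 to 3 h 10 probes were called, from 3 to 6 h 58, from 6 to 12 h 602, from 12 to 24 h 2287, from 24 to 48 h 5848, from 48 to 72 h 4226 and from 72 to 96 h 3622. These counts depended on the signal used: from 12 to 24 h, 24 to 48 h, 48 to 72 h and 72 to 96 h they were 704, 2847, 1562 and 779 with an offset of 0, 731, 2805, 1573 and 718 with the processed signals, and 312, 1668, 913 and 733 with Cy3 alone. The counts from 3 to 6 h and from 6 to 12 h were also far lower with an offset of 0, with the processed signals and with Cy3 alone. The steps differ in length, and the step from 12 to 24 h crosses the days. For the transient probes below, the comparison of 24 h with 0 h crosses the days too. The early steps moved with single arrays: from 3 to 6 h 13 probes were called without either 0 h array, 33 or 5 without either 6 h array and 20 without either 24 h array; from 6 to 12 h 303 or 298 without either 6 h array; and from 12 to 24 h 1247 or 1420 without either 24 h array. Within the second day, 48 to 96 h differed from 24 h for 12636 probes, 6955 higher and 5681 lower, whereas with Cy3 alone 4048 were higher and 4603 lower. Transient probes, set apart at 24 h in one direction from both 0 h and the end of the course, numbered 1131, with 707 higher and 424 lower at 24 h; without either 24 h array 621 or 573 were called, without either 0 h array 624 or 627, with the processed signals 301 and with Cy3 alone 151 (94 higher and 57 lower).

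Among probes that changed at least 2-fold between 0 h and the mean of 72 and 96 h, the median share of that change reached by the 963 risers was 8.44% at 12 h, 21.3% and 19.8% on the 24 h arrays and 60.2% at 48 h. The 559 fallers had reached 13.0%, 30.6% and 30.8%, and 76.2%. Single probes varied widely: on the first 24 h array the quartiles were 10.9% and 35.5% for risers and 15.9% and 62.1% for fallers. Under the alternatives run for these shares, the median at 24 h, averaged over its arrays, was 18.9% to 24.4% for risers and 28.4% to 36.7% for fallers. Among probes above the median of their mean signal at both ends, the fallers were not ahead at 24 h, with 22.4% and 19.5% against 23.0% and 20.9% for risers, in a split chosen after seeing the data.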

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

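Trend counts within each image analysis day, and all alternatives for steps, transient probes and shares, were chosen after seeing the data. Counts of late changes were the steadier ones: with ratios at an adjusted p under 0.05 and no fold limit, the counts at 48, 72 and 96 h, late, late against early and for the trend over all 12 arrays stayed within 1.5 times of the reported ones, and all 4 named probes kept their direction and their call under every alternative run, though not their size: with Cy3 alone Z00026066-1 changed by -5.53 in place of -3.87, and with no background correction Z00015331-1 by 2.23 in place of 3.13 and Z00036522-1 by -2.59 in place of -3.34. Early counts did not, and where no construction is named the cause was not tested. With a normexp offset of 0, 4 probes were called at 3 h, 62 at 6 h, 916 at 12 h, 4970 at 24 h and 148 early. Agilent's processed signals gave 4 at 3 h, 1 at 6 h, 901 at 12 h and 110 early. The deposited table gave 6 at 3 h, 1 at 6 h, 1056 at 12 h and 214 early. Median centring gave 271 at 6 h, 1123 at 12 h, 5000 at 24 h and 503 early. Cy3 alone gave 2 at 3 h, 0 at 6 h, 492 at 12 h, 2747 at 24 h, 5280 at 48 h, 8970 at 72 h, 194 early and 10747 late. Rises were 32.3% of the 6 h calls and 37.2% of the early calls with an offset of 0, and 75.3% of the early calls with Cy3 alone, against 54.7% and 51.5%. Array weights gave 1015 at 6 h. By construction, an adjusted p under 0.01 lowered the counts to 5 at 3 h, 74 at 6 h, 1004 at 12 h, 4572 at 24 h and 313 early. A limit of 2-fold left 4 at 3 h, 0 at 6 h, 45 at 12 h, 207 at 24 h, 693 at 48 h, 1201 at 72 h, 1975 at 96 h, 0 early, 1129 late, 1063 late against early and 6 for the trend per 24 h. On the replicated times alone, where early is 6 h only, 656 were called early. The trend was called for 2140 probes within the first day and 10154 within the second, on 6 arrays each. Leaving out 1 array at a time gave 4 to 14 at 3 h, 41 to 927 at 6 h, 1145 to 2652 at 12 h, 4817 to 8261 at 24 h, 8328 to 11206 at 48 h, 11250 to 14085 at 72 h, 12932 to 16200 at 96 h, 38 to 2354 early, 12467 to 16723 late, 11935 to 15296 late against early and 13869 to 16411 for the trend; a time left with 1 array was assumed to vary like the others. Aquantile changes no log ratio, so its equal counts say nothing about stability. With the replicate block, 7 were called at 3 h, 570 at 6 h, 948 early and 15567 late; deviations of same-numbered arrays had correlations from -0.04 to 0.16, so the numbers were not taken to pair samples. The mean over a gene's probes and the gene list tests were not run, for want of gene names, and a day block could not be fitted to comparisons with 0 h from 24 h on. The median net Cy3 signal, 97.0 to 221 units beside an offset of 50, limits the folds of dim probes. This median was lower on every array of the first image analysis day than on any of the second. The shrinkage by the offset may therefore differ between the days.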

Other observations

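In the last paragraph, the split by the mean of both ends was chosen after related results were seen, and the split by the mean over all arrays once the limit at both ends had been tested; its other tests were written before their results were seen, after the profiles of a few probes had been viewed. Of the tests before it, those of the image analysis day on probes that moved on from 24 h and on Cy5 calls, and the slope and the correlation of Cy5 with Cy3 changes, were chosen after the results were seen. Late against early called 14415 probes; of the 35 splits of the 8 treated arrays into 4 and 4, 1 gave as many, the real one, and the highest of the others gave 0. The real split passes the bound set for chance, but 1 in 35 is the smallest share this design can give. Every other split mixes early and late arrays, so a true difference would widen the spread within its groups and lower its calls. Chance is therefore thinly tested and not excluded. The real split is also the split by image analysis day, which this count does not exclude either.

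For the late calls against 0 h, the day was weighed as the whole cause. Of the 16136 probes, 10036 were also called in the same direction from 24 h to 48 to 96 h, inside the second day, though both comparisons share the late arrays. Movement inside the second day is how the 10036 were picked, so it is no separate test of them. A second test had no array in both. It took the 13503 probes called from 0 h to 48 h and the second 72 h array. Of these, 84.3% had the same sign from 24 h to the other 72 h array and 96 h, against 67.5% of all probes. This argues against the day as the whole cause over that set, though not for each probe in it. The test had first asked for 95%, a bound set for probes called in both comparisons. After the 84.3% was seen, the bound of 75% used for Cy5 was taken for this wider set. With 95% the day would have been left open. In a like test the Cy5 channel, with the same reference RNA on every array, reached 87.5% against 69.1% of all probes. The share alone therefore does not tie the change to treatment. Up to 24 h, day and time cannot be told apart for the probes that moved on. A further 421 were called in the opposite direction inside the second day, and 5679 had no call there, 267 of which were called early in the same direction. The change from 3 and 6 h to 12 h, on arrays with no part in late against 0 h, had the sign of the late change in 96.4% of the 421 and 73.5% of the 5679, against 57.5% of all probes. The first share passes the bound set for it, but it rests on the single 12 h array and excludes nothing, so day and treatment cannot be told apart for these 2 sets either.

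The Cy5 channel held the same reference RNA on every array and is the denominator of each ratio, so its calls are no data apart from the comparisons. By itself it called 9527 probes late against early in the fit of 2 groups, but 128 late against 0 h, 112 at 96 h and 1 at 24 h against 0 h, and 21 from 24 h to 48 to 96 h in the fit of 8 time groups. Of the 9527, 1.84% were over 4 times brighter in Cy3, against 0.719% of tested probes. As the 300 such probes can make up at most 3.15% of the calls, this share decides nothing, and Cy3 light read in the Cy5 channel stays open. Of the 6045 probes called without the first 72 h array and the 96 h array, 87.5% went on in the same direction from 24 h to those arrays, inside the second day, against 69.1% of all probes, which argues against the day as the whole cause. What else moved the channel stays open too, and no biological explanation was tested. Of the 9527, 4177 were also called in the ratio, 2212 with the same sign and 1965 with the opposite.

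Among probes over 4 times brighter in Cy3, the net Cy5 change followed the net Cy3 change inside the second day with a slope of 0.060. For the slopes given here, Cy5 signals were scaled to a common median over arrays, and Cy3 signals were left unscaled. The log2 changes of these probes had a correlation across probes of 0.830, which argues against the day. The Cy5 change also had a correlation of 0.458 with the change of the ratio. This correlation was 0.481 and 0.355 among probes 2 to 4 and 1 to 2 times brighter in Cy3. Among probes brighter in Cy5 it ranged from -0.016 to 0.120. The offset shrinks changes of the dimmer dye more, so an effect shared by both dyes could also leave a positive correlation. Effects shared by both dyes of a spot therefore stay open. Whether Cy3 light was read in the Cy5 channel cannot be told apart from other causes: among probes brighter in Cy5 the correlation reached 0.741, less than 0.1 below, where the test asked for more, and among probes 1 to 2 and 2 to 4 times brighter in Cy3 the slopes were 0.140 and 0.141, above that of the brighter ones. For Z00026066-1, the net Cy5 signal was 623 and 856 units at 0 h and 295 at 96 h.

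Fallers were nearer to their end point than risers at 24 h, by 9.30 and 10.9 percentage points on the 2 arrays. With processed signals, which carry no offset, the difference was at least 9.63 points, past the bound set for it. Those signals selected 1327 risers and 862 fallers, in place of 963 and 559. A like difference thus arose without an offset, but in another set of probes. For the probes of the main fit the offset stays open. From 24 to 48 h, inside the second day, it was 15.9 points, past the bound set for it, but this rests on the single 48 h array and excludes nothing, so the image analysis day stays open. Among probes with a net Cy3 signal of at least 200 at both ends it was 0.516 points at its smaller, though that limit removes probes that fell to a dim level. A split by the mean over all 12 arrays gave -1.74 points among the brighter probes, which decides nothing, since the 24 and 48 h arrays are part of that mean. Split by the mean of both ends, which leaves those arrays out, the difference was -1.38 points at its smaller among the brighter probes and 23.8 and 21.5 points among the dimmer. The difference is consistent with a property of dim probes, a hypothesis found in the same data, and no biological explanation was tested.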
